A study of Mus musculus with 4 samples.

How the data were processed

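Single-cell RNA sequencing was done on CD45-enriched cells sorted from orthotopic B6KPC3 pancreatic tumours of C57BL/6 mice. There were 4 libraries, 2 from mice given vehicle and 2 from mice given AT38, a compound known here only by its code name. Each library was a pool of 4 mice, so the library was the replicate and the p-values measure the spread between pooled libraries, not between mice or cells. Per the labels, tumours were 7 days old when treatment began, and AT38 was injected at 30 mg/kg per day for 7 days in 1% carboxymethyl cellulose. About 10000 cells were loaded per library with a target of 4000.

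The deposited matrices hold raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger 3.1.0 against mm10. The annotation release behind the gene IDs is not stated. The matrices list 31053 genes, and every barcode in them has 500 UMIs or more. Whether the cell caller or a later filter set that minimum is not stated. Gene positions were taken from GENCODE release M21 (GRCm38, the assembly of mm10) by Ensembl ID.

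Barcodes with at least 200 genes, at least 500 UMIs and at most 10% mitochondrial UMIs were kept. Of 18001 barcodes, 876 fell below the gene minimum and 2270 above the mitochondrial maximum. Doublets were scored against simulated pairs with scanpy's scrublet, and the highest scores were removed at 0.8% of barcodes per 1000 barcodes of the library. Scrublet's automatic threshold, which was not used, called 0.0278% of barcodes. The planned rate removed 683 barcodes (3.79%), which left 14242 cells. Counts were scaled to 10000 per cell, 2000 variable genes chosen per library and 30 principal components fed a graph of 15 neighbours, and Leiden clustering at resolution 1 gave 27 clusters. T and NK clusters were clustered again, which gave 15 sub-clusters. No integration between libraries was done, and the deposit holds no cell type names.

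A cluster was named from fixed marker lists when at least 3 markers of a type were detected in 10% of its cells or more and the type had the highest score (the mean log2 excess of its markers over the median cluster), and its 10 leading genes were checked. Clusters with 3 proliferation genes among the leading genes, and clusters with 2 leading genes of another class and no more of their own, stayed unnamed but remained in the denominator of cell shares. The marker lists were fixed in advance, and these thresholds for naming were worked out with the clusters in view. Monocyte-like and macrophage-like clusters were joined as mononuclear phagocytes. A class was tested if every library held at least 20 of its cells.

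Cell numbers per class were compared with the edgeR quasi-likelihood test, with the log of the library's kept cells as offset. The exact two-sided permutation p of each share is given beside it, and its smallest possible value with 2 against 2 libraries is 0.333. For genes, UMIs were summed per library over the cells of a class and tested with the edgeR quasi-likelihood test (robust, TMM, filterByExpr, two-sided). Benjamini-Hochberg adjustment ran over the genes tested in the class, with a threshold of 0.05. Printed errors of log2 fold changes are the model's standard errors, and errors of CPM (counts scaled to library size) and of shares are standard deviations over 2 libraries. Whether an effect differed between mononuclear phagocytes and neutrophils, or T cells, was tested as an interaction with library terms, since both classes came from the same libraries.

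The text tests 34 gene lists with 380 members, some of them shared. They cover nitric oxide and arginine metabolism, oxidase and superoxide handling, NRF2 targets, interferon responses, antigen presentation, costimulation, macrophage, neutrophil and T cell states, chemokines and cytokines, hypoxia, proliferation, the unfolded protein response, immediate early and mitochondrially encoded genes. Other lists hold markers of B, T, acinar, epithelial, fibroblast, endothelial, red blood, neutrophil and macrophage cells. Each list with 5 or more tested members was tested with limma's camera at a preset correlation between genes of 0.01 on log2 CPM (prior count 2). The result of camera with an estimated correlation, and of fry, stands beside it. Shares of cells with at least 1 UMI of Nos2 or Arg1 were taken after thinning every cell to 1000 UMIs, with B and T cells as background.

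Named genes followed a fixed rule. In each class these were the 10 largest rises and the 10 largest falls among genes with adjusted p under 0.05, a mean of at least 10 CPM, and both AT38 libraries on the same side of both vehicle libraries. Gene models without a name, immunoglobulin and T cell receptor segments and sex-linked markers were left out. Added were up to 4 members with the smallest p from each list discussed, and a few genes named whatever their value (Nos2, Arg1, Cybb and Hmox1 in myeloid cells, and Ifng, Gzmb, Prf1 and Pdcd1 in T and NK cells). Where 5 or fewer genes changed, those outside the rule were named after their values were seen. Some genes that the rule picks are not reported here. A gene is called abundant elsewhere when its mean CPM in another class with gene tests is at least 5 times that in the class, since free RNA from lysed cells can then reach it. The groups, tests, lists, rule for named genes and alternatives to be tried were set before the data were examined.

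Alternatives changed one choice at a time: cell filters, doublet removal, clustering resolution, size factors, test (DESeq2, limma-voom), gene filter, depth, list test, denominators, the replicate number as a block, and each library left out in turn. With a library left out, its arm holds 1 library, which is assumed to vary like the others. Alternatives chosen after seeing the data left out genes abundant elsewhere, counted a proliferating T and NK sub-cluster as CD8 T cells, took mixed clusters out of the denominator, and left out phagocytes with 10 or more Ctsk UMIs.

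The gene test was tested on simulated data with the depths of these libraries and the spread fitted to them as a smooth trend over genes. With 200 genes planted per run in 5 runs, it recovered 25.8% of 1.5-fold changes, 71.8% of 2-fold changes and 95.5% of 4-fold changes at phagocyte depth. At B cell depth those figures were 1.54%, 39.5% and 90.3%. With nothing planted it made 0 calls in each class, and the interaction test made 1 against neutrophils. The simulated counts follow the model of the tests, so these runs do not show the error rate on real genes. Planted lists of 15 genes were called in 5 of 5 runs with the preset correlation and in 0 of 5 with an estimated one, at folds of 1.5 and 2 in phagocytes, neutrophils and T cells. The simulated genes varied independently of each other, so these runs cannot tell which correlation suits the real lists. The estimated correlation missed every planted list, so a call lost with it does not tell whether a real list changed. A call with the preset correlation does not settle it either. A class made 2 times as frequent was called in 26 of 50 runs. Other classes were called 9 times in the 5 runs with more neutrophils, 4 times with more B cells and 0 to 3 times with any other class.

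The software was Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Gene tests were planned for mononuclear phagocytes, neutrophils, dendritic, B, T, CD8 T and NK cells and for all kept cells, and the other classes were left out of them. Counting error alone sets the limits given for counts of 0.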

Results

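Single-cell RNA sequencing was done on CD45-enriched cells, that is leukocytes with some remaining other cells, from pancreatic tumours grown in mice from the B6KPC3 line. The compound AT38 was compared with its vehicle in 2 libraries each, and each library pooled 4 mice. Vehicle 1 and vehicle 2 held 24875092 and 34386076 UMIs, and AT38 1 and AT38 2 held 30232623 and 24294215. After filtering, the libraries kept 2909, 4723, 3507 and 3103 cells in that order, with median UMIs per cell of 3582, 3005, 4009 and 4154. Per library, mononuclear phagocytes (monocytes and macrophages) held 2997511 to 6374413 UMIs and neutrophils 2242866 to 3877753. The UMIs of dendritic cells ranged from 5245761 to 7056716 and of B cells from 677923 to 1668236. Those of T cells ranged from 2614628 to 5112678, of CD8 T cells from 1048029 to 2716911 and of NK cells from 475110 to 837650.

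The study's title names nitrosative stress and cytotoxic T cells, and the share of each cell class among the kept cells was compared with AT38. Shares are relative, so a lower share of a large class raises the others. They do not give cell numbers in the tumour. Neutrophils were 35.6% ± 0.383 of the kept cells with vehicle and 27.3% ± 0.212 with AT38 (SD, n = 2). T cells were 18.2% ± 0.810 and 27.4% ± 5.95 (SD, n = 2), of which CD8 T cells, the cells that kill targets, were 7.38% ± 0.856 and 12.9% ± 3.64 of all kept cells. NK cells, innate killers, were 2.98% ± 0.129 and 4.79% ± 0.650, dendritic cells 10.1% ± 0.261 and 12.8% ± 0.0519, and B cells 10.8% ± 0.0778 and 6.18% ± 1.82. Mononuclear phagocytes were 14.4% ± 0.409 and 13.1% ± 3.02. Epithelial cells that came through the sort were 2.00% ± 0.579 and 1.12% ± 0.0112.

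None of these shares passed the edgeR test after adjustment. Of 13 broad and 21 fine classes 0 and 0 were past the threshold, 4 and 4 at an unadjusted p under 0.05, and 1 and 2 past it with limma on arcsine shares. The smallest adjusted p was 0.0892, for neutrophils (log2 fold change −0.38 ± 0.07, SE), NK cells (0.68 ± 0.14) and dendritic cells (0.34 ± 0.08). In each of these both AT38 libraries lay on one side of both vehicle libraries. For T cells the log2 fold change was 0.59 ± 0.20 (adjusted p = 0.116) and for CD8 T cells 0.80 ± 0.27 (adjusted p = 0.202). B cells stood at −0.81 ± 0.25 (adjusted p = 0.116) and phagocytes at −0.14 ± 0.21 (adjusted p = 0.608). The exact two-sided permutation test gives 0.333 at least with 2 against 2 libraries, so it cannot pass. The calls depended on which arm lost a library, since broad classes passed without AT38 1 or AT38 2, but none without vehicle 1 or vehicle 2. With 1 library in an arm, the spread comes from the pair of the other arm alone. For B, T and NK cells and phagocytes the vehicle libraries lay closer together than the AT38 libraries, while for neutrophils and dendritic cells the reverse held. These passes therefore do not point to a single deciding library. Without AT38 1 and without AT38 2, T cells were at 0.79 and 0.34, neutrophils at −0.39 and −0.38 and NK cells at 0.81 and 0.53. In the same order dendritic cells were at 0.34 and 0.35 and B cells at −1.15 and −0.54. The phagocyte value was −0.40 (adjusted p = 0.0108) without AT38 1 and 0.076 (adjusted p = 0.479) without AT38 2. CD8 T cells passed without AT38 1 (1.05), with the replicate number as a block (0.79), up to 20% mitochondrial UMIs (0.63), at least 500 genes (0.75), Leiden resolution 0.5 (0.80) and named immune cells as denominator (0.80). Their adjusted p ranged from 0.000209 to 0.386 over 13 alternatives. With that denominator neutrophils, NK, dendritic, T and B cells passed too (adjusted p = 0.0456 for each), and with at least 500 genes neutrophils and dendritic cells.

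**Figure D1:**
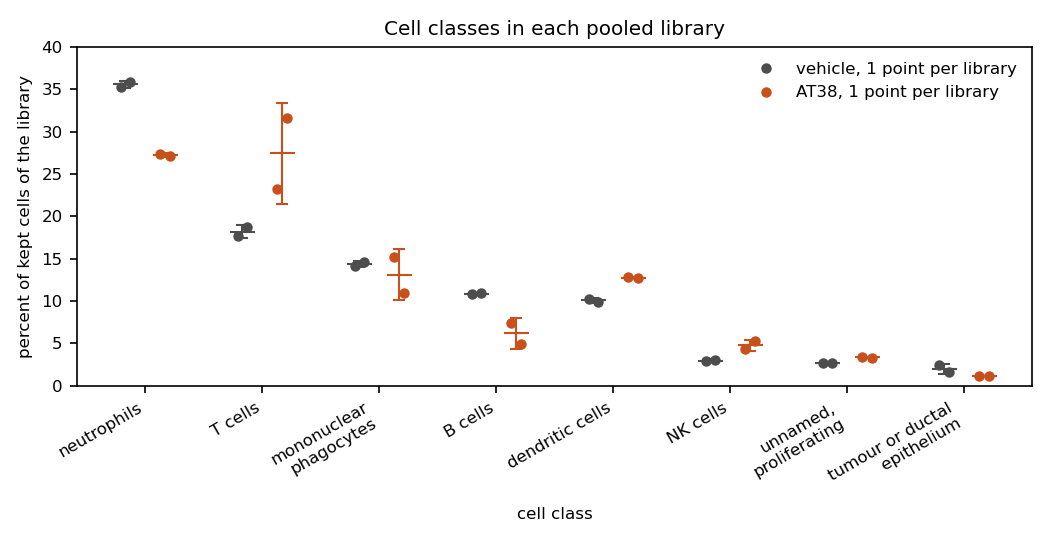
Share of kept cells (percent) per class, with 1 point per library and the mean and SD of each group. Neutrophils averaged 35.6% with vehicle and 27.3% with AT38, and T cells 18.2% and 27.4%.

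In mononuclear phagocytes, the class that can make both nitric oxide and arginase, the comparison addressed what AT38 does to myeloid cells. Interferon-induced genes, MHC class II genes and genes of alternatively activated macrophages were called higher with AT38 as lists, and hypoxia genes lower. These calls were lost with an estimated correlation (adjusted p = 0.592 or 0.635). That variant also missed the planted lists in simulation, so here and below a call lost with it does not tell whether a list changed. Of the 18 genes of the type I interferon response, the antiviral programme, 10 rose, 0 fell and 8 did not pass, and 17 rose when adjusted over the list alone (median log2 fold change 0.85, camera adjusted p = 1.93e-18). With an estimated correlation this list had an adjusted p = 0.592. Ifnb1, which encodes interferon beta, rose from 8.71 ± 0.161 to 33.8 ± 10.5 CPM (SD, n = 2), a log2 fold change of 1.92 ± 0.24 (SE). Its 351 UMIs lay in 97 phagocytes, with 32.5% of them in 5 cells. Ifit2, an interferon-induced inhibitor of translation, rose by 1.77 ± 0.28, Irf7, a regulator of interferon genes, by 0.87 ± 0.12 and Bst2, which tethers budding virus, by 0.70 ± 0.11. Bst2 no longer passed with any of the 4 libraries left out, and Irf7 without vehicle 2 or AT38 1. Of 19 tested genes of the interferon gamma response 3 rose, 0 fell and 16 did not pass, and 10 rose when adjusted over the list alone (median 0.32, camera adjusted p = 1.18e-06). The list had an adjusted p = 0.592 with an estimated correlation. The 3 that rose included Cxcl9, a chemokine that draws activated T cells (from 231 ± 5.63 to 452 ± 70.7 CPM, SD, n = 2), and the interferon-induced GTPase Iigp1 (1.01 ± 0.14).

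Antigen presentation by MHC class II, which displays peptides to CD4 T cells, was called higher in phagocytes as a list. Of 10 members 4 rose and 6 did not pass, and 7 rose when adjusted over the list alone (median 0.47, camera adjusted p = 0.000102). With an estimated correlation the MHC class II list had an adjusted p = 0.635. The 4 were H2-Eb1 (0.74 ± 0.08), H2-Ab1 (0.68 ± 0.09), H2-Aa (0.64 ± 0.08) and the invariant chain gene Cd74 (0.65 ± 0.10). In monocyte-like clusters alone they did not pass, at 0.053, 0.10, 0.032 and 0.046 in that order. These 4, Clec10a and Mgl2 were also among the leading genes of clusters of dendritic cells, and H2-Ab1 stood at 5720 CPM in dendritic cells and 3218 in phagocytes. Of dendritic cell genes looked up after the values were seen, Flt3 stood at 5.93 ± 1.47 and 6.61 ± 0.191 CPM in phagocytes (SD, n = 2). Cd209a stood at 14.6, 17.2, 48.0 and 4.43 CPM in vehicle 1, vehicle 2, AT38 1 and AT38 2. For MHC class I presentation 0 of 12 members passed and 1 rose when adjusted over the list alone (median 0.18, camera adjusted p = 0.0150, and with an estimated correlation adjusted p = 0.628). For costimulation 0 of 10 passed and 1 rose when adjusted over the list alone (median 0.35, camera adjusted p = 0.0134, and with an estimated correlation adjusted p = 0.592). Of 13 genes of alternatively activated macrophages, 5 rose, 0 fell and 8 did not pass, and 10 rose when adjusted over the list alone (median 0.78, camera adjusted p = 1e-07). With an estimated correlation they had an adjusted p = 0.592. They included Cd163, a haemoglobin scavenger receptor (1.77 ± 0.25), and the lectins Clec10a (0.96 ± 0.15, and 0.28 in monocyte-like clusters alone) and Mgl2 (1.06 ± 0.16). The complement genes C1qc (0.74) and C1qa (0.64) rose. Of 10 general macrophage markers these 2 rose, 8 did not pass, and 6 rose when adjusted over the list alone (median 0.50, camera adjusted p = 5.56e-06, with an estimated correlation adjusted p = 0.592).

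Chemokine genes of phagocytes moved in both directions. Of 8 chemokines that draw monocytes, 3 rose, 2 fell and 3 did not pass, and 4 rose and 2 fell when adjusted over the list alone (median 0.31). The camera adjusted p was 0.0348, and with an estimated correlation adjusted p = 0.592. Ccl8 rose most, from 145 ± 27.1 to 626 ± 12.3 CPM (SD, n = 2), a log2 fold change of 2.12 ± 0.13 (SE, adjusted p = 4.39e-05). Ccl12 rose by 1.47 ± 0.14, and Ccl9 and Ccl6 fell by 0.76 and 0.61. Of 6 tested chemokines that draw T cells, Cxcl9 rose, 5 did not pass, and 4 rose when adjusted over the list alone (median 0.42, camera adjusted p = 0.00195, with an estimated correlation adjusted p = 0.592). The other large rises included the secreted nuclease Dnase1l3 (2.00), the receptor Tlr12 (1.95) and the interferon-induced GTPase Gbp2b (1.90). They also took in the scavenger receptor Marco (1.83, with 64.8% of its UMIs in 5 cells), complement C6 (1.82) and the secreted phospholipase Pla2g2d (1.71, with 42.3% of its UMIs in 5 cells). Pla2g2d passed in 0 of 4 fits with a library left out.

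The list of hypoxia and glycolysis genes was called lower in phagocytes, a call lost with an estimated correlation (adjusted p = 0.592). The lipid droplet gene Hilpda fell (−0.63), and no longer passed with any of the 4 libraries left out. It was 1 of 14 tested, 13 did not pass, and 10 fell when adjusted over the list alone (median −0.37, camera adjusted p = 2.64e-06). The value of Pgk1, a glycolytic enzyme, was −0.45 (adjusted p = 0.0546). It passed in 10 of 18 alternatives, DESeq2 and the replicate block among them (adjusted p from 0.00128 to 1.0). Of 14 tested targets of NRF2, the regulator of the oxidative stress response, thioredoxin (Txn1) fell by 0.55, 13 did not pass, and 3 fell when adjusted over the list alone (median −0.32, camera adjusted p = 0.00226, and with an estimated correlation adjusted p = 0.739). The largest fall was in Ctsk, a protease that degrades collagen, from 198 ± 27.0 to 3.15 ± 0.366 CPM (SD, n = 2). Of its vehicle UMIs 96.7% lay in 7 phagocytes with 33 to 552 Ctsk UMIs each, and without them its log2 fold change was −1.13 ± 0.41 (adjusted p = 0.385). The fall of the matrix protease Mmp9 (−2.34) also rested on them (−0.54, adjusted p = 0.844 without them). Fn1, which encodes fibronectin, fell by 1.42 ± 0.10, the ubiquitin ligase gene Rnf128 by 2.27 ± 0.25 and the chemokine Cxcl14 by 1.86. The matrix gene Ecm1 fell by 1.29, the interleukin 36 gene Il1f9 by 1.24 and osteopontin (Spp1) by 1.13. The neutrophil chemoattractant Cxcl3 fell by 1.75 ± 0.12. Cxcl3, Il1f9 and Mmp9 were at least 5 times more abundant in another class. The same held for Spp1 and Ecm1 in epithelial cells and Rnf128 in innate lymphoid cells, classes without gene tests.

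In all, 114 of 10827 genes tested in phagocytes changed, 72 higher and 42 lower (1029 at an unadjusted p under 0.05). All 114 had both AT38 libraries on one side of both vehicle libraries. Chance gives that order with a share of 0.333, but these genes were picked by a test on the same libraries. The order therefore adds no support to the calls. The list of B cell markers was called lower in phagocytes. Of 6 tested markers Ebf1 fell (−2.67, adjusted p = 0.0493, no longer passing without vehicle 1, AT38 1 or AT38 2), 5 did not pass and 3 fell when adjusted over the list alone (median −1.94, camera adjusted p = 4.9e-06, with an estimated correlation adjusted p = 0.592). All 6 were at least 5 times more abundant in another class. Camera called 12 of 30 lists, and 0 held with an estimated correlation (1 at an unadjusted p under 0.05) or with fry (7 at an unadjusted p under 0.05). The number of changed genes was 45 without vehicle 1, 74 without vehicle 2, 31 without AT38 1 and 67 without AT38 2. Of the 37 changed genes named for phagocytes 17, 13, 22 and 12 no longer passed in that order. With Leiden resolution 0.5, 19 no longer passed. In macrophage-like clusters alone 203 genes changed, and 3 of the 37 no longer passed. In monocyte-like clusters alone 14 changed, and of 29 tested 25 no longer passed, among them Cxcl9 (0.10), Ccl12 (0.58), Fn1 (−0.41), Spp1 (−0.071), Hilpda (−0.035), C1qa (0.34), Ifnb1 (3.58) and Iigp1 (1.59). Ccl8, Ccl12, Cxcl9, Cxcl3, Ecm1, Fn1, Ifnb1, H2-Eb1, Rnf128 and Ctsk passed with each library left out. The list calls lost were those of MHC class I (without vehicle 2 or AT38 1) and NRF2 targets (without vehicle 1 or AT38 1). Also lost were T cell chemokines (without AT38 1), costimulation (without AT38 2) and monocyte chemokines (without vehicle 1, AT38 1 or AT38 2).

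**Figure D2:**
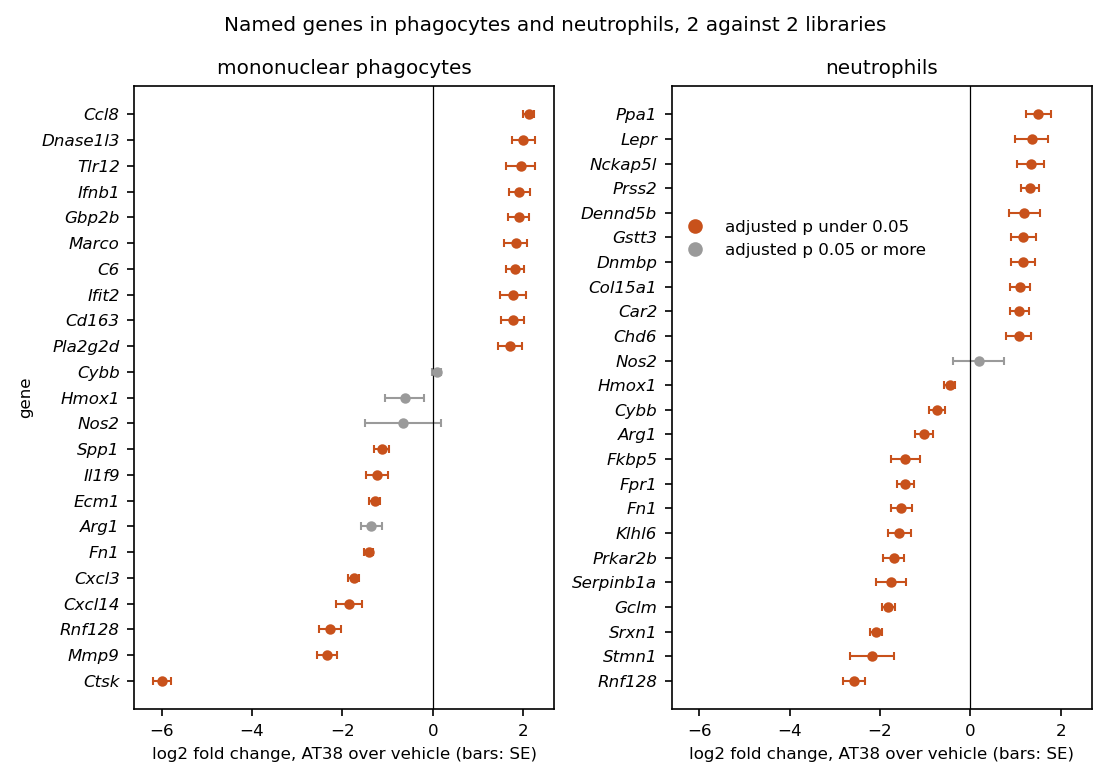
Log2 fold change of AT38 over vehicle with its SE for named genes in mononuclear phagocytes and neutrophils. Ccl8 stood at 2.12 in phagocytes, and Srxn1 at −2.08 and Gclm at −1.81 in neutrophils.

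In neutrophils, short-lived phagocytes that make reactive oxygen species, the list of oxidative stress genes was called lower with AT38. Of 15 targets of NRF2, 0 rose, 10 fell and 5 did not pass, and 14 fell when adjusted over the list alone (median −0.59, camera adjusted p = 1.01e-08). NRF2 targets had an adjusted p = 0.491 with an estimated correlation. Srxn1, the sulfiredoxin that restores oxidised peroxiredoxins, fell from 164 ± 18.3 to 38.4 ± 5.60 CPM (SD, n = 2), a log2 fold change of −2.08 ± 0.14 (SE, adjusted p = 1.62e-08). Gclm, a subunit of the enzyme that makes the precursor of glutathione, fell from 90.0 ± 6.06 to 25.6 ± 1.52 CPM (SD, n = 2). The cystine importer Slc7a11 fell by 0.62 ± 0.08, ferritin heavy chain (Fth1) by 0.59 ± 0.08 and haem oxygenase (Hmox1) by 0.45 ± 0.12. The oxidase subunit gene Cybb fell by 0.73 ± 0.17, while its list of oxidase and superoxide genes did not pass (2 fell and 7 did not pass, median −0.22, camera adjusted p = 0.0566).

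Lists of genes by which neutrophils suppress or inflame were called lower as well. Of 11 tested genes of myeloid suppression 5 fell and 6 did not pass, and 6 fell when adjusted over the list alone (median −0.31, camera adjusted p = 0.00717, and with an estimated correlation adjusted p = 0.491). Arg1 and Arg2, which encode the arginases, fell by 1.02 ± 0.20 and 0.58 ± 0.09, the lectin Clec4e by 0.36 and the calprotectin gene S100a8 by 0.44. Of 13 tested inflammatory cytokine genes 4 fell and 9 did not pass, and 4 fell when adjusted over the list alone (median −0.19, camera adjusted p = 0.0231, and with an estimated correlation adjusted p = 0.491). Among the 4 were Cxcl3 (−1.24) and the NF-κB inhibitors Tnfaip3 (−0.59) and Nfkbia (−0.38), which are themselves induced by NF-κB. The maturation genes Lcn2 (−0.51) and Cd177 (−0.36) fell. Of 10 in their list 2 fell and 8 did not pass, and 2 fell when adjusted over the list alone (median −0.48, camera adjusted p = 0.000725, and with an estimated correlation adjusted p = 0.491). The granule gene Ngp in that list was at −2.24 (adjusted p = 0.294), and passed without AT38 1 (−2.99) or AT38 2 (−1.76) and with DESeq2 (−2.25). Lcn2 and Ngp were among the leading genes of a small neutrophil cluster whose share is given below. Whether that share carried their lower values was not tested. Other falls were in S100a9 (−0.31) and Hdc (−0.34). With S100a8, 3 of 10 neutrophil markers fell, 7 did not pass, and 5 fell when adjusted over the list alone (median −0.29, camera adjusted p = 0.0213, and with an estimated correlation adjusted p = 0.654). For genes of tumour neutrophils the median was −0.01 (camera adjusted p = 0.621).

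The lists of interferon genes and MHC class I presentation were called higher in neutrophils, calls lost with an estimated correlation (adjusted p = 0.491 to 0.662). Isg15 (0.54) and Zbp1 (0.62) rose. Of 16 tested type I interferon genes 3 rose, these 2 among them, 13 did not pass, and 7 rose when adjusted over the list alone (median 0.37, camera adjusted p = 0.0172, and with an estimated correlation adjusted p = 0.662). Of 17 tested interferon gamma genes 5 rose, 12 did not pass and 5 rose when adjusted over the list alone (median 0.25, camera adjusted p = 0.0213, and with an estimated correlation adjusted p = 0.654), among them the GTPase Gbp4 (0.95). The proteasome genes Psmb8 (0.45) and Psmb9 (0.43) and the peptide transporter Tap1 (0.42) rose, Tap1 no longer passing with any of the 4 libraries left out. Of 12 MHC class I genes these 3 rose, 9 did not pass, and 4 rose when adjusted over the list alone (median 0.17, camera adjusted p = 0.0215, and with an estimated correlation adjusted p = 0.491). The regulator Klf2 (−0.66), which neutrophils share with naive T cells, fell. Of 5 tested genes of naive and memory T cells 3 fell, 2 did not pass, and 3 fell when adjusted over the list alone (median −0.67, camera adjusted p = 0.0273, and with an estimated correlation adjusted p = 0.491). Hmgb2 (−0.60) and Stmn1 (−2.18, with 47.6% of its UMIs in 5 cells) fell. Of 10 tested proliferation genes these 2 fell, 8 did not pass, and 3 fell when adjusted over the list alone (median −0.83, camera adjusted p = 0.00351, and with an estimated correlation adjusted p = 0.654).

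The largest other falls in neutrophils were those of Rnf128 (−2.57 ± 0.25), the protease inhibitor Serpinb1a (−1.76, with 35.8% of its UMIs in 5 cells) and the kinase subunit Prkar2b (−1.69). They went on with Klhl6 (−1.57), Fn1 (−1.52), the formyl peptide receptor Fpr1 (−1.44) and the glucocorticoid-induced gene Fkbp5 (−1.44). The largest rises were in the pyrophosphatase gene Ppa1 (1.51 ± 0.28), the leptin receptor Lepr (1.36, with 60.9% of its UMIs in 5 cells), Nckap5l (1.33) and Prss2 (1.33), which encodes a trypsinogen of acinar cells. They also included Dennd5b (1.20), the glutathione transferase Gstt3 (1.18), Dnmbp (1.17), the collagen gene Col15a1 (1.10), carbonic anhydrase Car2 (1.09) and Chd6 (1.08). Arg1, Car2, Chd6, Dennd5b, Fn1, Klf2, Klhl6 and Stmn1 were at least 5 times more abundant in another class. Of classes without gene tests, the same held for acinar cells with Prss2 (48235 CPM, against 69.8 in neutrophils), epithelial cells with Ppa1, fibroblasts with Col15a1, mast cells with Serpinb1a and innate lymphoid cells with Dnmbp and Rnf128. The shares of clusters within neutrophils were not tested. The cluster with Il1a and Cxcl2 among its leading genes held 22.3% ± 2.58 of neutrophils with vehicle and 41.0% ± 1.00 with AT38 (SD, n = 2). The cluster marked by Retnlg and Slpi held 31.2% ± 3.33 and 19.96% ± 0.702, and that marked by Slc7a11 and G0s2 held 35.0% ± 4.09 and 27.9% ± 0.0450. The smallest, with Ngp, Camp, Lcn2 and Ltf among its leading genes, held 1.65% ± 0.262 and 0.766% ± 0.242. It had 15, 31, 9 and 5 cells in vehicle 1, vehicle 2, AT38 1 and AT38 2.

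Of 8425 genes tested in neutrophils 416 changed, 122 higher and 294 lower (1510 at an unadjusted p under 0.05). All 416 were without overlap between the groups, an order that chance gives with a share of 0.333. Since they were picked by a test on the same libraries, that order adds no support. Camera called 10 of 27 lists, and 0 held with an estimated correlation (0 at an unadjusted p under 0.05) or with fry (6 at an unadjusted p under 0.05). The number of changed genes was 136 without vehicle 1 and 259 without vehicle 2, and 148 with doublets kept and 207 with DESeq2. Of the 43 changed genes named for neutrophils 20, 16, 6 and 7 no longer passed without vehicle 1, vehicle 2, AT38 1 and AT38 2, and 18 passed in each, among them Srxn1, Gclm, Slc7a11, Fth1, Arg1 and Rnf128. Lepr was at 0.62 and Dennd5b at 0.65 without AT38 2, Car2 at 0.68 and Chd6 at 1.70 without vehicle 2, and Hmox1 at −0.29 without vehicle 1. With doublets kept 23 no longer passed, among them Fth1, Arg1 (−0.59), Stmn1 (−0.34), Fkbp5 (−0.87), Tap1 (0.26) and Chd6 (0.69), and Ppa1 was at 0.97. With at least 500 genes Prss2 was at 0.27 and did not pass. The calls of NRF2 targets, inflammatory cytokines, myeloid suppression and maturation held in each. Those of type I interferon, interferon gamma and neutrophil markers ended without vehicle 2 or AT38 2, of MHC class I without vehicle 2, AT38 1 or AT38 2, of naive and memory genes without vehicle 2 and of proliferation without vehicle 1.

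Nitrosative stress itself was not measured here. Among the genes of nitric oxide and arginine metabolism, Nos2 makes nitric oxide and Arg1 consumes the same substrate. After thinning every cell to 1000 UMIs, Arg1 was found in 35.2% ± 0.681 of phagocytes with vehicle and in 17.2% ± 0.680 with AT38 (SD, n = 2), a difference of −18.1 percentage points (exact permutation p = 0.333, the smallest possible). In neutrophils the share was 2.02% ± 0.326 and 0.891% ± 0.410 (SD, n = 2), a difference of −1.13 points (exact permutation p = 0.333). Background for Arg1 was 0.842% and 0.510% in T cells and 0.873% and 0.214% in B cells, lower with AT38 in both. The phagocyte share lay far above it and the neutrophil share near it. Nos2 was found in 1.40% ± 0.853 and 0.961% ± 0.557 of phagocytes (exact permutation p = 0.667, SD, n = 2), against 0.0326% and 0.0054% of T cells and 0.0492% and 0% of B cells, and its difference of −0.437 points became 0.165 without vehicle 1. In neutrophils Nos2 was found in 0.491% ± 0.0751 and 0.300% ± 0.196 (exact permutation p = 0.667, SD, n = 2). Median UMIs per cell before thinning were 7516 and 7143.5 in phagocytes, 2087 and 2212.5 in neutrophils, 2870 and 3467 in B cells and 3893 and 4367 in T cells (vehicle and AT38). On summed UMIs the phagocyte log2 fold change was −1.36 ± 0.23 for Arg1 (adjusted p = 0.121) and −0.65 ± 0.84 for Nos2 (adjusted p = 0.922), with both AT38 libraries below both vehicle libraries for Arg1 and overlap for Nos2. Arg1 passed in phagocytes without AT38 1 (−1.70) or AT38 2 (−1.09), with DESeq2 (−1.36), the replicate block (−1.38), no filter on low counts (−1.37) and Leiden resolution 0.5 (−1.41). Its adjusted p ranged from 8.1e-24 to 1.0 over all alternatives. In neutrophils Nos2 was at 0.18 ± 0.55 (adjusted p = 0.908), and −1.32 without AT38 2. The whole list did not pass, with 0 of 13 members past the threshold in phagocytes (median −0.09, camera adjusted p = 0.0898) and 2 of 11 falling in neutrophils (median −0.14, camera adjusted p = 0.197). Cybb and Hmox1 were at 0.08 ± 0.10 (adjusted p = 0.902) and −0.62 ± 0.43 (adjusted p = 0.802) in phagocytes, and Cybb at −0.041 without AT38 2.

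**Figure D3:**
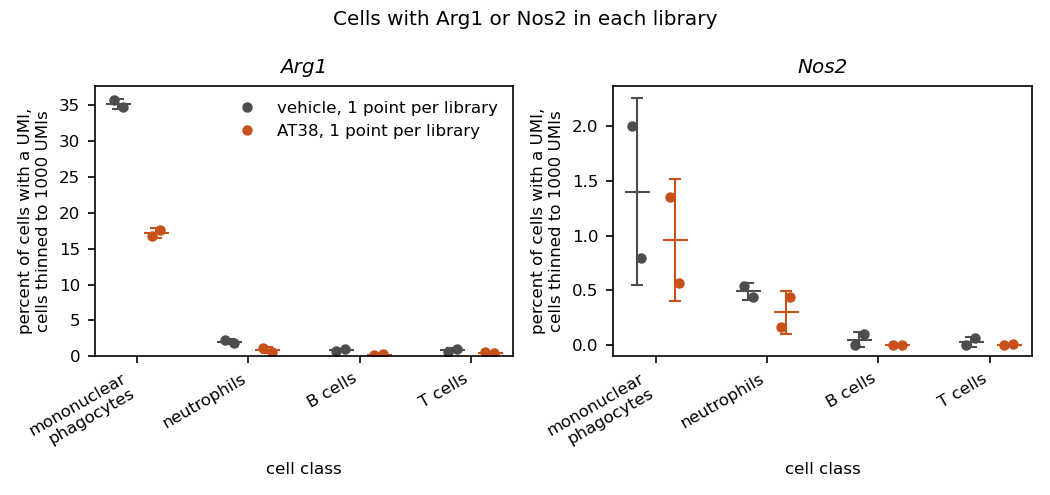
Share of cells (percent) with at least 1 UMI of Arg1 or Nos2 after thinning to 1000 UMIs, by class, with 1 point per library and the group means. Arg1 was found in 35.2% of vehicle phagocytes and 17.2% of AT38 phagocytes.

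In dendritic cells, which prime T cells, type I interferon genes were called higher as a list and 5 single genes fell. Of 18 type I interferon genes 0 passed and 3 rose when adjusted over the list alone (median 0.49, camera adjusted p = 8.53e-08, with an estimated correlation adjusted p = 0.599), with Isg15 at 0.74 (adjusted p = 0.128) and Irf7 at 0.87 (adjusted p = 0.128). The lists of interferon gamma (median 0.21), MHC class II (0.21, with H2-Ab1 at 0.26 and adjusted p = 0.537) and MHC class I (0.15, with Psmb9 at 0.42 and adjusted p = 0.334) were also called higher. They had 0 members past the threshold and 1, 0 and 1 rising when adjusted over the list alone, and with an estimated correlation adjusted p = 0.599, 0.622 and 0.599. Fn1 (−1.69 ± 0.16), the lectins Clec4d (−1.69 ± 0.14) and Clec4e (−1.01 ± 0.12) and the chemokine Cxcl2 (−0.70 ± 0.08) fell. So did Ighm, the heavy chain of immunoglobulin M (−2.68 ± 0.12), which was named after its values were seen. All 5 genes that fell were at least 5 times more abundant in another class. Lists of other cells were called lower in dendritic cells, calls lost with an estimated correlation (adjusted p = 0.599 or 0.622 for each), with medians of −1.72 for neutrophil maturation, −1.42 for neutrophil markers, −1.60 for B cell markers (Ms4a1 at −1.76, adjusted p = 0.128) and −0.70 for T cell markers. The same holds for others, with −0.31 for naive and memory T cell genes, −0.64 for myeloid suppression, −0.62 for monocyte chemokines, −0.27 for inflammatory cytokines and −0.10 for immediate early genes. Of these lists, inflammatory cytokines and myeloid suppression had 1 member that fell and the others 0, and adjusted over the list alone the number falling was 4, 4, 2, 0, 0, 2, 2, 4 and 2 in that order. The neutrophil genes G0s2 and Hdc were at −0.998 (adjusted p = 0.128) and −1.40 (adjusted p = 0.451). Without AT38 1, Isg15 (0.73), Irf7 (0.82), Psmb9 (0.52), Ms4a1 (−1.76), G0s2 (−1.21) and Hdc (−1.97) passed, and without AT38 2 Isg15 (0.74) and Hdc (−1.02). Isg15, G0s2 and Hdc passed with DESeq2, Isg15, Irf7 and G0s2 with the replicate block, and all 6 with no filter on low counts.

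Of 11183 genes tested in dendritic cells 5 changed (766 at an unadjusted p under 0.05, and 31 with DESeq2). Camera called 13 of 30 lists, and 0 held with an estimated correlation (lowest adjusted p = 0.599, and 2 at an unadjusted p under 0.05) or with fry (6 at an unadjusted p under 0.05). The number of changed genes was 10 without vehicle 1, 18 without vehicle 2, 327 without AT38 1 and 34 without AT38 2. Clec4e no longer passed without vehicle 1, and Cxcl2 without vehicle 1 or vehicle 2. With doublets kept Fn1, Clec4e, Cxcl2 (−0.45) and Ighm no longer passed, and with up to 20% mitochondrial UMIs Fn1, Clec4e and Ighm. With at least 500 genes or Leiden resolution 0.5 Clec4e and Cxcl2 no longer passed, and with resolution 2 Clec4e. Of the 13 list calls 3, 2, 1 and 5 were lost without vehicle 1, vehicle 2, AT38 1 and AT38 2.

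In T cells the question was whether AT38 raises their killing programme. Ccl5, a chemokine made by activated and cytotoxic T cells, rose from 1923 ± 88.1 to 2547 ± 156 CPM (SD, n = 2), a log2 fold change of 0.41 ± 0.07 (SE, adjusted p = 0.0130). It was the 1 gene of 12 tested cytotoxic genes that rose, 11 did not pass, 3 rose when adjusted over the list alone, and the list did not pass (median 0.16, camera adjusted p = 0.0642). CD8 T cells were 197, 377, 361 and 479 of 513, 887, 815 and 982 T cells in vehicle 1, vehicle 2, AT38 1 and AT38 2. Ccl5 was among the leading genes of CD8 T sub-clusters, but not among the 3 genes that changed in CD8 T cells. Whether the mix of T cells carried its rise was not tested. Ifng was at 0.31 ± 0.10 (adjusted p = 0.427), Gzmb at 0.07 ± 0.23 (adjusted p = 0.987), Prf1 at 0.14 ± 0.13 (adjusted p = 0.887) and the inhibitory receptor Pdcd1 at −0.24 ± 0.10 (adjusted p = 0.612). Gzmb was at −0.26 without AT38 1 and Prf1 at −0.017 without vehicle 1. Ifng passed without vehicle 2 (0.53), and its adjusted p ranged from 0.00310 to 0.872 over all alternatives. The medians of exhaustion (0.10, camera adjusted p = 0.311) and activation genes (−0.15, camera adjusted p = 0.311) did not pass.

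The list of naive and memory T cell genes was called lower in T cells. Of 10 members 1 fell, Klf2, which keeps T cells circulating (−0.45), 9 did not pass, among them Tcf7 (−0.32, adjusted p = 0.216), and 6 fell when adjusted over the list alone (median −0.29, camera adjusted p = 0.000474, with an estimated correlation adjusted p = 0.777). Also lower were the survival gene Bcl2 (−0.47), the kinase gene Txk (−0.48) and the glucocorticoid-induced gene Tsc22d3 (−0.61). Further falls were those of Clu (−1.99 ± 0.26), Scin (−1.65), Thbs1 (−1.34), Tnfaip2 (−1.27), Fn1 (−1.24), Gda (−1.17) and Cd83 (−0.69). Cd83, Fn1, Gda, Thbs1, Tnfaip2 and Cxcl3 were at least 5 times more abundant in another class. Of classes without gene tests, the same held for epithelial cells with Clu (9308 CPM, against 18.1 in T cells) and mast cells with Scin. Inflammatory cytokine genes were called lower (1 of 13 fell, Cxcl3 at −2.22, 12 did not pass, 4 fell when adjusted over the list alone, median −0.23, camera adjusted p = 0.00904, with an estimated correlation adjusted p = 0.777). Myeloid suppression was called lower (0 of 9 passed, 4 fell when adjusted over the list alone, median −0.47, camera adjusted p = 0.00337, with an estimated correlation adjusted p = 0.777). Neutrophil markers were called lower too (0 of 7 passed, 3 fell when adjusted over the list alone, median −0.44, camera adjusted p = 0.000474, with an estimated correlation adjusted p = 0.777), with S100a9 at −0.83 (adjusted p = 0.0502). S100a9 passed without vehicle 2 (−1.10), AT38 1 (−0.71) or AT38 2 (−0.99) and in 10 of 15 alternatives in all, and Tcf7 without vehicle 2 (−0.39). Also higher were AY036118 (0.61), Lars2 (0.45), the mitochondrial leucyl-tRNA synthetase gene, and AC149090.1 (0.41). Lars2 and AY036118 were among the leading genes of a T cell sub-cluster with few UMIs (median 1087 per cell), which was counted as CD8 T cells. It held 17, 20, 28 and 42 cells in vehicle 1, vehicle 2, AT38 1 and AT38 2, of 513, 887, 815 and 982 T cells.

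Of 10314 genes tested in T cells 18 changed, 5 higher and 13 lower (710 at an unadjusted p under 0.05). All 18 were without overlap between groups, which selection by the test favours. Camera called 4 of 28 lists, and 0 held with an estimated correlation (0 at an unadjusted p under 0.05) or with fry (4 at an unadjusted p under 0.05). The number of changed genes was 65 without vehicle 2, 123 without AT38 1 and 41 without AT38 2. Of the 16 changed genes named for T cells 6, 4, 0 and 5 no longer passed without vehicle 1, vehicle 2, AT38 1 and AT38 2. With up to 20% mitochondrial UMIs 9 no longer passed, Clu, Lars2, AY036118 and Thbs1 (−0.86) among them, and with Leiden resolution 2 it was 11, Klf2, Lars2 and AY036118 among them. With at least 500 genes 5 no longer passed, among them Thbs1 (−0.80), and Fn1 was at −0.83 without vehicle 2. With each library left out Ccl5, Clu, AY036118, Thbs1 and Tnfaip2 passed, as did the call of neutrophil markers. Inflammatory cytokines were lost without vehicle 1 or vehicle 2 and the other 2 lists without vehicle 1.

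In CD8 T cells, the killers among T cells, Clu, which encodes a secreted chaperone, fell by 2.42 ± 0.34 on the log2 scale (adjusted p = 0.000509), from 32.1 ± 11.5 to 5.49 ± 1.26 CPM (SD, n = 2). Clu is the leading gene of the epithelial cluster (9308 CPM), whose share of kept cells was 2.00% with vehicle and 1.12% with AT38. Ifng was at 0.16 ± 0.12 (adjusted p = 0.986), Gzmb at 0.02 ± 0.68 (adjusted p = 0.999), Prf1 at 0.07 ± 0.15 (adjusted p = 0.999) and Pdcd1 at −0.23 ± 0.12 (adjusted p = 0.986). Gzmb was at −0.38 without vehicle 2 and −0.61 without AT38 1, and Prf1 at −0.032 without vehicle 1 and −0.14 without AT38 1. Cxcl2 passed without vehicle 2 (−0.82) or AT38 1 (−0.85), and Klf2 without AT38 1 (−0.67). Both passed with no filter on low counts and with the proliferating sub-cluster included. Naive and memory genes were called lower with 0 of 10 members past the threshold and 4 falling when adjusted over the list alone (median −0.42, camera adjusted p = 0.00350, with an estimated correlation adjusted p = 0.902), and Klf2 was at −0.54 (adjusted p = 0.0857). Inflammatory cytokines (median −0.26, 0 of 13 passed, 4 fell when adjusted over the list alone, with Cxcl2 at −0.65) and myeloid suppression (median −0.35, 0 of 8 passed, 0 adjusted over the list alone) were called lower too, with an estimated correlation adjusted p = 0.902 and 0.902. The cytotoxic and exhaustion lists had medians of 0.08 and 0.06 (camera adjusted p = 0.748 for both). Of 8981 genes 3 changed (432 at an unadjusted p under 0.05). The others were the gene models Gm42418 (0.48 ± 0.09) and Gm10076 (−0.58 ± 0.10), named after their values were seen, and both no longer passed without vehicle 1. Gm42418 was another leading gene of the sub-cluster with a median of 1087 UMIs. With up to 20% mitochondrial UMIs none of the 3 passed, and with thinning, at least 500 genes or Leiden resolution 2 neither gene model did. Gm42418 did not pass with the replicate block either. Camera called 3 of 25 lists, 0 of them with an estimated correlation (0 at an unadjusted p under 0.05) or fry (1 at an unadjusted p under 0.05). The number of genes was 18 without vehicle 1, 25 without vehicle 2, 32 without AT38 1 and 22 without AT38 2. All 3 lists were lost without vehicle 1 and without AT38 2, and myeloid suppression also without vehicle 2.

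In NK cells, Xcl1, a chemokine that draws cross-presenting dendritic cells, rose from 1226 ± 135 to 1905 ± 318 CPM (SD, n = 2), a log2 fold change of 0.63 ± 0.12 (adjusted p = 0.0389). Cxcl2, at least 5 times more abundant in another class, fell by 0.83 ± 0.16 (adjusted p = 0.0389). Ifng was at −0.27 (adjusted p = 0.835), Gzmb at −0.06 (adjusted p = 0.995), Prf1 at −0.12 (adjusted p = 0.954) and Pdcd1 at −2.62 ± 0.63 (adjusted p = 0.186). Gzmb was at 0.24 without vehicle 1 and 0.092 without AT38 2, and Pdcd1 passed without vehicle 2 (−3.10) or AT38 2 (−4.19), with the replicate block (−2.61) and with no filter on low counts (−2.59). Of 6654 genes 3 changed (389 at an unadjusted p under 0.05, and 1 with DESeq2). Camera called 0 of 21 lists (7 at an unadjusted p under 0.05, and 1 with fry), the nearest being T cell markers (median −0.44, camera adjusted p = 0.0633). The number of genes was 16 without vehicle 1, 26 without vehicle 2, 8 without AT38 1 and 6 without AT38 2, and Xcl1 and Cxcl2 no longer passed without AT38 2. The gene model Gm42418 (0.59 ± 0.11), named after its values were seen, no longer passed without AT38 1 or AT38 2, and rose in CD8 T and B cells too. Xcl1 and Cxcl2 did not pass with DESeq2, Xcl1 with up to 20% mitochondrial UMIs, at least 500 genes or Leiden resolution 2, and Cxcl2 with thinning. Gm42418 did not pass with up to 20% mitochondrial UMIs or the replicate block.

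In B cells, Ly6c2, an interferon-inducible surface protein gene, rose from 30.9 ± 13.6 to 134 ± 8.16 CPM (SD, n = 2), a log2 fold change of 2.12 ± 0.24 (adjusted p = 0.000946). The metallothionein gene Mt1 (1.57 ± 0.21), Tppp3 (3.62 ± 0.62) and the survival gene Bcl2a1b (1.23 ± 0.20) rose as well, and these 3 were at least 5 times more abundant in another class. Type I interferon genes were called higher with 0 of 7 past the threshold and 4 rising when adjusted over the list alone (median 0.87, camera adjusted p = 1.27e-05, and with an estimated correlation adjusted p = 0.805), with Bst2 at 0.87 (adjusted p = 0.266). The interferon gamma list (median 0.42, 0 of 16 passed, 1 rose when adjusted over the list alone) and hypoxia genes (median 0.31, 0 of 12 passed, 0 adjusted over the list alone) were called higher too, calls lost with an estimated correlation (adjusted p = 0.805), with Hilpda at 0.64 (adjusted p = 0.636). Immediate early genes, which tissue dissociation also induces, were called lower (median −0.28, 0 of 15 passed, 5 fell and 1 rose when adjusted over the list alone), with Hspa1a at −0.88 (adjusted p = 0.110). Bst2 passed without vehicle 1 (1.18) or AT38 2 (0.88), and Hspa1a without vehicle 1 (−0.69), vehicle 2 (−1.06) or AT38 2 (−0.97). Both passed with the replicate block (0.85 and −0.89) and with no filter on low counts, and Hspa1a with thinning. With an estimated correlation the adjusted p was 0.805 for each of the 4 lists (1 of 25 at an unadjusted p under 0.05, and 1 with fry). Of 8193 genes 5 changed, all higher (482 at an unadjusted p under 0.05), and the number was 122 without vehicle 1, 63 without vehicle 2, 25 without AT38 1 and 46 without AT38 2. The gene model Gm42418 (0.50 ± 0.08), named after its values were seen, no longer passed without AT38 1 or AT38 2. With doublets kept Ly6c2 was at 0.45, Mt1 at 0.19 and Bcl2a1b at 0.87, and none of them passed. Mt1 was at 0.13 with up to 20% mitochondrial UMIs and did not pass. Tppp3, Bcl2a1b and Gm42418 did not pass with DESeq2, and Tppp3 not with limma-voom. The hypoxia call was lost without vehicle 2 or AT38 2, and the immediate early call without vehicle 2 or AT38 1.

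Summed over all kept cells, values carry both cell shares and expression per cell. T cell markers were called higher with AT38 as a list. Of 8, Cd3g (0.51) and Cd3d (0.45) rose, which no longer passed without vehicle 1, vehicle 2 or AT38 2, 6 did not pass, and 7 rose when adjusted over the list alone (median 0.37, camera adjusted p = 2.64e-05, with an estimated correlation adjusted p = 0.339). Of 12 cytotoxic genes 3 rose, Ccl5 (0.56), Nkg7 (0.49) and Ifng (0.39, adjusted p = 0.0423), 9 did not pass, and 7 rose when adjusted over the list alone (median 0.36, camera adjusted p = 0.000127, with an estimated correlation adjusted p = 0.339). Neutrophil markers were called lower as a list. Of 10, 4 fell, among them S100a8 (−0.74), 6 did not pass, and 7 fell when adjusted over the list alone (median −0.63, camera adjusted p = 7.04e-07, with an estimated correlation adjusted p = 0.403). Of 15 NRF2 targets 8 fell, among them Srxn1 (−1.20) and Slc7a11 (−0.81), 7 did not pass, and 13 fell when adjusted over the list alone (median −0.48, camera adjusted p = 1.2e-08, with an estimated correlation adjusted p = 0.383). Of 18 type I interferon genes 4 rose, among them Ifit2 (0.69), 14 did not pass, and 12 rose when adjusted over the list alone (median 0.42, camera adjusted p = 2.12e-07, with an estimated correlation adjusted p = 0.339). Of 12 myeloid suppression genes 5 fell, among them Arg2 (−0.91), 7 did not pass, and 5 fell when adjusted over the list alone (median −0.64, camera adjusted p = 0.000120, with an estimated correlation adjusted p = 0.349).

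The largest rises over all cells were in H2-M2 (1.35), the NK receptor gene Klra8 (0.89), Dnase1l3 (0.85), Phf11a (0.79), Clec9a, a receptor of cross-presenting dendritic cells (0.73), Ifi213 (0.70), Tnni2 (0.68), Rnaset2b (0.62) and Iigp1 (0.58). Iigp1 passed in 0 of 4 fits with a library left out, and Rnaset2b in 1 of 4, that without AT38 1. Large falls were those of Ctsk (−4.35), Fpr1 (−1.71), Cxcl3 (−1.63), Il1f9 (−1.58), Rnf128 (−1.48), Rdh12 (−1.44), the granule genes Ltf (−1.41) and Slpi (−1.25), and Sox9 (−1.23), a regulator of ductal cells. Of 14504 genes 262 changed, 60 higher and 202 lower (2152 at an unadjusted p under 0.05). Of 33 lists 18 were called, 0 of them with an estimated correlation (lowest adjusted p = 0.339, and 3 at an unadjusted p under 0.05) and 6 with fry. The number of genes was 167 without vehicle 1. Of the 28 changed genes named over all cells 12, 8, 5 and 8 no longer passed without vehicle 1, vehicle 2, AT38 1 and AT38 2, and 15 with the replicate block. Of the 18 lists 3, 4, 2 and 4 were lost in that order of left-out libraries.

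The remaining lists include those of cells that the sort should remove. In phagocytes the median of lipid-associated tumour macrophage genes was −0.18 (camera adjusted p = 0.417). Over all kept cells it was −0.40, with 1 of 12 falling and 3 when adjusted over the list alone (camera adjusted p = 0.00183, with an estimated correlation adjusted p = 0.339). In phagocytes the median of oxidase genes was −0.04 (camera adjusted p = 0.448) and of inflammatory cytokines −0.06 with 3 of 14 falling (camera adjusted p = 0.0957). Over all kept cells the median of the unfolded protein response was −0.02 (camera adjusted p = 0.282), of mitochondrially encoded genes −0.09 (camera adjusted p = 0.237), of acinar genes 2.41 (camera adjusted p = 0.0878), of epithelial genes −0.46 (camera adjusted p = 0.149), of fibroblast genes −0.25 (camera adjusted p = 0.654) and of endothelial genes −0.20 (camera adjusted p = 0.549). The red blood cell list had fewer than 5 tested members in each class and was not tested.

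**Figure D4:**
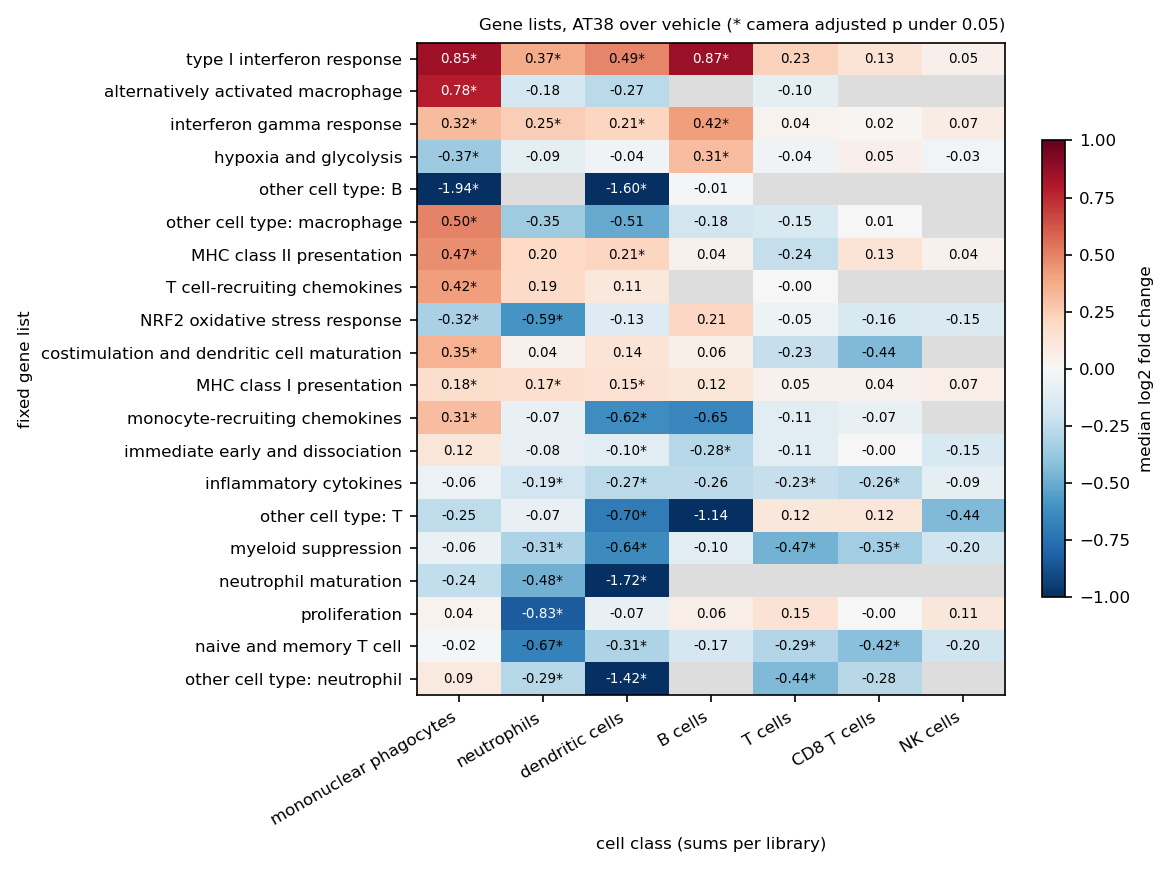
Median log2 fold change of AT38 over vehicle for each gene list (vertical) and cell class (horizontal), with a star where the camera adjusted p was under 0.05. The type I interferon list stood at 0.85 in phagocytes and 0.37 in neutrophils, and NRF2 targets at −0.32 and −0.59.

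Whether AT38 acted differently on different cells was tested as the difference between its effects in phagocytes and in another class of the same libraries. Against neutrophils 124 of 10790 genes differed, 86 with the higher value in phagocytes and 38 with the lower (1284 at an unadjusted p under 0.05). Against T cells 27 of 11428 differed, 12 higher and 15 lower (789 at an unadjusted p under 0.05). Ccl8 (difference 1.65), Cxcl9 (0.80) and Ifit2 (1.28) were higher in phagocytes relative to neutrophils. Srxn1 differed by 1.48, since it was at −0.60 in phagocytes (adjusted p = 0.631) and fell by 2.08 in neutrophils. Against T cells H2-Eb1 and Cd74 differed by 0.97, and Rnf128 by −2.61, since it was at 0.35 in T cells (adjusted p = 0.878). The number of genes was 372 against neutrophils without AT38 1, and against T cells 75 without vehicle 2, 147 without AT38 1 and 43 without AT38 2.

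By annotation on GRCm38, Gm42418, Gm10076 and AY036118 are lincRNAs and Ighm is an immunoglobulin constant gene, while the genes placed below are protein-coding. Gm42418 and AY036118 overlap on chromosome 17, on opposite strands. Arg1 (ENSMUSG00000019987) lies on chromosome 10 from 24915221 to 24927484, and Nos2 (ENSMUSG00000020826) on chromosome 11 from 78920787 to 78960254. Ccl8 (ENSMUSG00000009185) lies on chromosome 11 from 82115185 to 82116799, Ifnb1 (ENSMUSG00000048806) on chromosome 4 from 88522025 to 88522774 and Cxcl9 (ENSMUSG00000029417) on chromosome 5 from 92321347 to 92328079. Srxn1 (ENSMUSG00000032802) lies on chromosome 2 from 152105516 to 152111376, Gclm (ENSMUSG00000028124) on chromosome 3 from 122245557 to 122270732, Ctsk (ENSMUSG00000028111) on chromosome 3 from 95499256 to 95509362 and Rnf128 (ENSMUSG00000031438) on chromosome X from 139563316 to 139673145. Ccl5 (ENSMUSG00000035042) lies on chromosome 11 from 83525778 to 83530518, Clu (ENSMUSG00000022037) on chromosome 14 from 65968483 to 65981547, Xcl1 (ENSMUSG00000026573) on chromosome 1 from 164931644 to 164935527 and Ly6c2 (ENSMUSG00000022584) on chromosome 15 from 75108158 to 75111970.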

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

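Of the tests below, those on the Ctsk-high cells and those on the cluster shares alone were chosen after the results were seen. The rules for the 2 tests of a mix of clusters were written before them, replaced after the outcomes were seen and then restored as first written. What sets these results apart is a test of whether AT38 effects differ between classes of the same libraries. It called 124 genes for phagocytes against neutrophils and 27 against T cells.

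Among these, with the effect in phagocytes minus that in neutrophils on the log2 scale, the nuclease Dnase1l3 differed by 2.10, the protease inhibitor Serpinb1a by 2.60, Ccl8 by 1.65, the kinase subunit Prkar2b by 1.51, the sulfiredoxin Srxn1 by 1.48, Ifit2 by 1.28 and Cxcl9 by 0.80. Klf2 differed by 0.75, Hmgb2 by 0.68 and Tnfaip3 by 0.57, 3 genes that fell in neutrophils. The difference was −4.84 for Ctsk, −2.13 for Cxcl14, −2.10 for Mmp9, −1.96 for Car2, −1.56 for Ppa1, −0.999 for osteopontin (Spp1) and −0.53 for Cxcl3. Against T cells it was −2.61 for Rnf128, −2.49 for Mmp9, −1.21 for Ecm1, −0.88 for Hilpda and 0.97 for H2-Eb1 and for Cd74. It was 0.98 for S100a9 and 0.95 for Cd83, which did not pass in phagocytes (0.14 and 0.27). Whether RNA from other cells set the T cell values was not tested. Without the 7 Ctsk-high phagocytes below, Mmp9 was at −0.54 in phagocytes (adjusted p = 0.844).

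Ctsk fell in phagocytes from 198 to 3.15 CPM. Of the vehicle Ctsk UMIs 96.7% lay in cells with 10 or more of them, so a few cells of another kind within the class may carry the fall. These were 2 cells in vehicle 1, 5 in vehicle 2 and 0 of 874 AT38 phagocytes (a share of up to 0.343% by counting error alone). Doublets of a phagocyte with another named class are argued against, since the highest Ctsk count in another named class was 12 and the lowest in these cells 33, while an unnamed cell reached 40. Whether AT38 removed these cells or chance capture of rare cells missed them cannot be told apart, because the exact permutation p was 0.333, the smallest that 2 against 2 libraries can give.

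NRF2 targets were called lower in neutrophils with a median of −0.59, where 10 of 15 fell, 5 did not pass, and the call was lost with an estimated correlation (adjusted p = 0.491). RNA from other cells is argued against, since the loss of UMIs per neutrophil exceeded the whole level in B cells for 8 of the 14 members with fewer UMIs. By the rule written before that test, a mix of neutrophil clusters may account for part of the fall. The median was as weak as −0.098 in the cluster with Il1a and Cxcl2 among its leading genes, which met that rule. In the others it was −0.40, −0.37 and −0.50. A weak median in a single cluster also arises where the effect differs between clusters, so the rule cannot separate these. The cluster shares alone are argued against as the whole cause, since with each cluster's vehicle levels they give a median of −0.116 (SD over members 0.175). Within the other clusters 1 of 15, 2 of 14 and 2 of 15 members had a positive value, in the order above, so the fall was also present inside them. What lowered the targets there was not tested, and an effect of AT38 stays open.

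Type I interferon genes were called higher in phagocytes with a median of 0.84 over the edgeR fold changes, where 10 of 18 rose, 8 did not pass, and the call was lost with an estimated correlation (adjusted p = 0.592). RNA from other cells is argued against, since the gain of UMIs per phagocyte exceeded the whole level in T cells for 17 of 18 members. A shift in cluster shares is argued against, since with vehicle levels it gives a median of 0.0149 (SD over members 0.0281). A mix of phagocyte clusters in the sense of the test set in advance, a rise missing from some cluster, cannot be told apart from a general rise, because the weakest cluster had 0.306, between the bounds of that test, and the others 1.07 and 1.05. An effect of AT38 on interferon signalling thus stays open as a hypothesis.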

How the results depend on the processing

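The alternatives without genes abundant elsewhere, with the proliferating T and NK sub-cluster, without mixed clusters and without Ctsk-high phagocytes were chosen after seeing the data, and the others were planned. Of 2214 alternative values for 140 changed genes, 1817 kept direction and threshold, 397 kept direction and no longer passed, and 0 reversed. Each changed gene had both AT38 libraries on one side of both vehicle libraries, so leaving out a library could hardly reverse it. The 0 therefore adds little support. Of 602 alternative values for 64 called lists 415 kept both and 187 no longer passed, the most with an estimated correlation (64 of 64) and with fry (58). The estimated correlation also missed the planted lists in simulation. A left-out library leaves its arm with 1, which is assumed to vary like the others. Of the 33 named genes that did not pass, 72 of 539 alternative values passed. At the depth and spread of each class a planted 1.5-fold change was found in 1.54% of cases in B cells, 11.7% in NK cells and up to 42.0% in T cells, so smaller changes were mostly not detectable. Except where fewer genes, cells or libraries enter by construction, the cause was not tested.

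Left out 1 at a time, the libraries gave 31 to 74 changed genes in phagocytes, 136 to 416 in neutrophils, 10 to 327 in dendritic cells, 25 to 122 in B cells, 23 to 123 in T cells, 18 to 32 in CD8 T cells, 6 to 26 in NK cells and 167 to 345 in all cells. Called lists ranged from 10 to 17, 5 to 14, 10 to 18, 4 to 7, 2 to 10, 0 to 6, 0 to 2 and 15 to 19 in that order. Genes that differed from phagocytes ranged from 92 to 372 for neutrophils and 30 to 147 for T cells, and called shares from 0 to 6 (broad) and 0 to 4 (fine). The thinned Arg1 difference ranged from −18.5 to −17.6 points in phagocytes and −1.42 to −0.843 in neutrophils, and that of Nos2 from −1.04 to 0.165 and −0.329 to −0.0524. Signs turned for Nos2 in phagocytes (−1.36 to 0.45, positive without vehicle 1) and neutrophils (−1.32 to 0.95, negative without AT38 2). They turned for Cybb in phagocytes (−0.041 to 0.20, negative without AT38 2) and the phagocyte share (−0.40 to 0.076, positive without AT38 2). Gzmb ranged from −0.26 to 0.35 in T cells (negative without AT38 1), −0.61 to 0.53 in CD8 T cells (negative without AT38 1, and −0.38 without vehicle 2) and −0.32 to 0.24 in NK cells (positive without vehicle 1, and 0.092 without AT38 2). Prf1 ranged from −0.017 to 0.39 in T cells (negative without vehicle 1) and −0.14 to 0.30 in CD8 T cells (negative without AT38 1, and −0.032 without vehicle 1).

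Up to 20% mitochondrial UMIs gave Gzmb −0.0041 in T cells, Prf1 −0.046 in CD8 T cells, 0 genes in CD8, 1 in NK, 11 in T and 3 in dendritic cells, and 5 fine shares. At least 500 genes per cell gave Gzmb −0.039 in T cells, Ifng −0.018 and Prf1 −0.040 in CD8 T cells, 1 gene in CD8 T cells, and 2 broad and 2 fine shares. Without doublet removal Ifng was −0.078 and Prf1 −0.20 in CD8 T cells, Prf1 −0.090 in T cells and Nos2 −0.16 in neutrophils, with 9 genes in B cells, 3 in dendritic cells, 206 in phagocytes and 148 in neutrophils. Leiden resolution 0.5 gave Gzmb −0.0069, Ifng −0.023 and Prf1 −0.21 in CD8 T cells, Prf1 −0.067 in T cells and Gzmb 0.035 in NK cells, with 31 genes in T cells, 3 in dendritic cells and 40 in phagocytes, and 2 fine shares. Resolution 2 gave Gzmb −0.0079 and Prf1 −0.13 in CD8 T cells and 1 gene there. Macrophage-like clusters alone gave 203 genes and monocyte-like clusters 14. The proliferating sub-cluster gave Gzmb −0.034 and Prf1 −0.13 in CD8 T cells, Prf1 −0.027 in T cells, and 9 and 30 genes.

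DESeq2 gave 2 genes in B cells, 1 in NK cells, 478 in all cells, 31 in dendritic cells and 207 in neutrophils. Limma-voom gave Gzmb −0.0072 in CD8 T cells and Nos2 −0.20 in neutrophils. No filter on low counts gave 43 genes in B, 18 in CD8 T, 10 in NK, 65 in T, 193 in dendritic cells, 387 in phagocytes and 775 in all cells. It gave 116 and 210 that differed from T cells and neutrophils, and 7, 5 and 9 lists in B, NK and T cells. Thinning to the smallest library gave Gzmb −0.0010 in T cells, Prf1 −0.022 in CD8 T cells and 1 gene there. The estimated correlation gave 0 lists in B, CD8 T, T and dendritic cells, phagocytes, neutrophils and all cells. Fry gave 0 in these but 6 in all cells. Without genes abundant elsewhere there were 0 lists in CD8 T, 1 in T and 6 in dendritic cells, and 2 genes in B, 8 in CD8 T, 0 in dendritic cells and 178 in phagocytes. Taking the replicate number as a block, though deviations of like numbers hardly matched (correlations of −0.0946 to 0.220 across genes, which are not independent replicates), gave Gzmb −0.022 in CD8 T cells and 3 lists in NK cells. It gave 83 genes in B, 18 in NK, 46 in T and 66 in dendritic cells, 229 in phagocytes and 120 in all cells, and 6 fine shares. Of the shares, TMM on cell counts gave the phagocyte share 0.015, limma on arcsine shares called 1 broad and 2 fine, and named immune cells as denominator gave 5 and 2. At 2000 UMIs the Arg1 difference was −19.9 points in phagocytes and −2.53 in neutrophils and that of Nos2 −0.419 in neutrophils, and unthinned −19.5 and −2.40 for Arg1 and −1.30 for Nos2 in phagocytes.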

Other observations

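The tests of the Ctsk-high cells in this part were chosen after the result was seen. Rnf128, which encodes a ubiquitin ligase, fell in phagocytes (−2.27 ± 0.25, SE) and in neutrophils (−2.57 ± 0.25), and was at 0.35 in T cells (adjusted p = 0.878). Its CPM went from 52.2 ± 0.471 to 11.5 ± 5.39 in phagocytes and from 35.7 ± 0.282 to 5.93 ± 1.69 in neutrophils (SD, n = 2), and it passed with each library left out in both classes. Among the fine classes, cross-presenting dendritic cells (cDC1) were 1.29% ± 0.321 of kept cells with vehicle and 2.13% ± 0.415 with AT38 (SD, n = 2, adjusted p = 0.202), and CD4 T cells 4.22% ± 0.493 and 6.28% ± 1.55 (adjusted p = 0.248). The cDC1 share passed with the replicate block (log2 fold change 0.73) and with up to 20% mitochondrial UMIs (0.86), and the CD4 T cell share with the block (0.57) and without AT38 1 (0.82). The unnamed proliferating cells were 2.70% ± 0.0189 and 3.35% ± 0.0952 (adjusted p = 0.294 among the fine classes and 0.112 among the broad).

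The 7 Ctsk-high phagocytes held a median of 20860 UMIs, and the other phagocytes 7323. A candidate explanation of their genes is an osteoclast-like programme, since 7 of 12 detected osteoclast genes other than Ctsk were at 4 or more times the level in the other phagocytes. The list was written before that test, and whether these 7 cells carry CD45 was not tested. Slc9b2 was at 1223 times, Mmp9 at 174, Atp6v0d2 at 42.8, Acp5 at 39.8, Nfatc1 at 9.11, Ocstamp at 6.63 and Tnfrsf11a at 5.43, while Dcstamp was at 3.86, Tcirg1 at 3.16, Car2 at 2.75 and Itgb3 at 1.91. Oscar, which is not among the 7, had 15 UMIs in 1 of these cells and 0 CPM in the other phagocytes, so it has no ratio. Mmp9 and Car2 were also found in neutrophils.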
